A study of Bos taurus with 18 samples.

How the data were processed

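Gene expression was measured by RNA sequencing in 18 libraries from 2 lines labelled as bovine fibroblasts at 3 stages with 3 libraries each. Per the labels, RNA was extracted with RNeasy mini kits, libraries were made with NEBNext Ultra II RNA kits and read as single reads on a NextSeq, and the genome build was UMD3.1. The deposited table holds expected counts per Ensembl gene, made with salmon and merged to genes, as its file name says. The aligner, the salmon version, the annotation release and the strand setting are not given in the sources used here. Between 1.01% and 7.18% of the values of a library were not whole, and all were rounded before the tests. The table has 24596 genes with gene names from the file. Of these, 4628 have an Ensembl identifier as name, and 15055 have a name found in a table of RefSeq genes. That table was used only for the chromosome, order and length of genes.

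Total counts (M for 1e+06) were 1.46, 1.47 and 1.42 M in the Holstein-like primary libraries, 14.1, 12.9 and 13.3 M in the senescent and 11.9, 11 and 14 M in the immortalized ones. Simmental-like totals were 20.2, 23.2 and 18.4 M for primary, 20.7, 19.0 and 19.4 M for senescent and 18.2, 20.1 and 19.8 M for immortalized libraries. A gene with 0 counts could be present at up to 3 counts, which is 2.11 CPM in the smallest library and 0.129 CPM in the largest. Counts of Holstein-like primary libraries differed from each other by little more than counting noise (chi-square per gene 1.17 to 1.21), as did Simmental-like senescent libraries 1 and 2 (1.20), whereas Holstein-like senescent libraries differed by 200 to 1170.

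Each line was fitted on its own 9 libraries with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, a robust quasi-likelihood fit and F-test for each pair of stages, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors are the size of the log2 change over the square root of F. The difference between lines was tested as an interaction on all 18 libraries. Genes changed in both lines were counted among genes tested in both, beside the number expected if the lines were independent. Gene lists fixed before the data were examined (34 lists, 716 of 768 symbols found in the table) were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 and at least 5 tested members. An estimated correlation and fry were run beside it. The test designs, the alternatives and the rule for named genes were also fixed before the data were examined, and sets of organ marker genes were written afterwards.

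Named genes follow 4 parts of a rule. A fixed set of 10 genes linked to senescence, telomeres and growth is given in every comparison where it was measured, except 1 that is not reported here. Per comparison the 6 genes that rose most and the 6 that fell most are named among those past the threshold with a given symbol, a mean of at least 10 CPM in the higher group and groups that do not overlap. In the Holstein-like comparisons only some of these genes are named. Of each list up to 4 members past the threshold with the largest change are named. For shared and differing changes the 6 largest per direction under the same conditions in both lines are named. Genes on the sex chromosomes that tell the sexes apart were left out. Where a group had 0 counts, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts, the ratio is given with a 95% counting interval. Differences between lines with such a group are given in the same way, as the ratio of the Holstein-like to the Simmental-like change, and genes were ranked by fitted values.

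Alternatives were other scalings (edgeR RLE, upper quartile, total count), no filter and a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the 6 libraries compared or all 18 in one fit, a 2-fold minimum, and leaving out each library. After the data were seen, thinning the Holstein-like libraries to the smallest one, summing the 3 Holstein-like primary libraries and summing Simmental-like senescent libraries 1 and 2 were added.

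The steps were tested on simulated data with the dispersions of each line. Of 100 genes changed 4-fold, the Simmental-like fits recovered 89, 88 and 87, with 3, 6 and 7 false calls. The Holstein-like fits recovered 0 of 100, and 79 when given the Simmental-like dispersions. A list of 30 genes shifted 1.5-fold was recovered in all 6 comparisons, with 0 of the other lists called. The simulated genes varied independently of each other, so this cannot show how often lists are called falsely when their members vary together. Groups of neighbouring genes, each of them all tested genes placed on 1 chromosome, were tested on their median change. The test used 1000 permutations of the gene order and was chosen after the data were seen. A shift of 0.5 put into 1 group was recovered as 0.508.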

Results

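By the labels, RNA was sequenced from fibroblasts of 2 cattle lines, 1 Holstein-like and 1 Simmental-like, that had been kept in culture over a long period. Each line was sampled at 3 stages, called primary, senescent and immortalized, with 3 libraries per stage and 18 libraries in total. The columns of the stages carry different culture names, so stage and named culture could not be separated: BDF-20-3B-4, BDF-20-MultiXray-Ctrl and BF-13 for Simmental-like primary, senescent and immortalized libraries, and BEF, BF-15-P9 and BF-15-P23 for the Holstein-like ones. The counts covered 24596 genes. The Simmental-like libraries held 18.2 to 23.2 M counts. The senescent and immortalized Holstein-like libraries held 11 to 14.1 M, and the 3 primary ones held 1.42 to 1.47 M (M for 1e+06). Levels are CPM (counts per 1e+06 counts) after TMM scaling, as mean ± SD over n = 3 libraries, and changes are log2 values ± SE. P-values measure the spread between these libraries, which may be technical, because the labels call the replicates biological without saying whether they came from separate cultures.

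The Simmental-like libraries carried the transcripts of cultured fibroblasts, and in 8 of the 9 Holstein-like libraries a set of organ genes took more of the counts than the fibroblast set. A set of 7 fibroblast culture genes that includes COL1A1, VIM and MKI67 took 4.85% to 8.64% of the counts in each Simmental-like library. In the libraries labelled Holstein-like primary the same set took 0.0423%, 0.0422% and 0.0421%, while 7 skeletal muscle genes took 15.8%, 15.9% and 15.8%. MYH1, a fast muscle myosin, was their most abundant gene. Heart genes took 5.82% of Holstein-like senescent library 1. Liver genes, among them ALB and FGB, took 15.9% of senescent library 2, 13.1% of senescent library 3 and 13.9% of immortalized library 1. Kidney genes took 0.978% of immortalized library 2, above its fibroblast share of 0.124%. In immortalized library 3 the fibroblast set took 4.94% and the highest organ set 0.724%. Among the 6 senescent and immortalized Holstein-like libraries, 1 lay nearest to a library of its own stage by correlation across genes, against 9 of 9 Simmental-like libraries. The Holstein-like results are therefore given by the labels of the libraries, with these markers beside them.

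**Figure D1:**
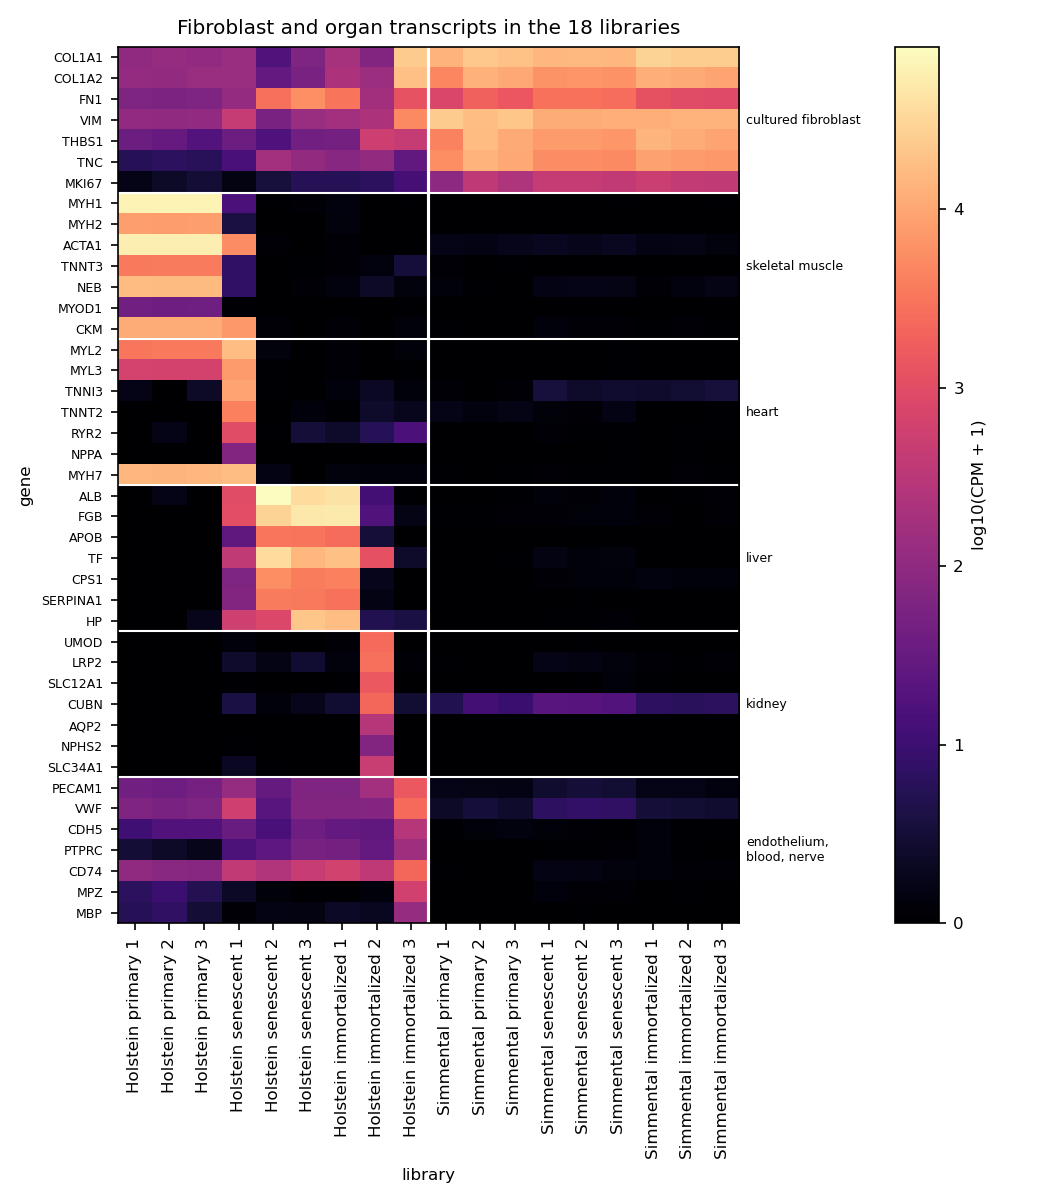
Heatmap of log10(CPM + 1) for 7 fibroblast culture genes and 5 sets of 7 organ genes (vertical axis) in each of the 18 libraries (horizontal axis). Skeletal muscle genes take 15.8% to 15.9% of the counts in the Holstein-like primary libraries, and the fibroblast set takes 4.85% to 8.64% in the Simmental-like ones.

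The first Simmental-like comparison asked how senescent cells differed from primary ones. The sources used here do not say whether both stages came from 1 animal and body site, so stage and source cannot be told apart. Some genes of body position, picked after their values were seen, differed between them. GATA4 stood at 0.228 CPM in primary and 44.8 in senescent libraries, and BARX1 at 10.96 CPM and 1 count. The growth inhibitor genes went in opposite directions. CDKN2B rose from 17.7 ± 3.6 to 85.3 ± 0.96 (2.26 ± 0.15, adjusted p = 8.4e-06) and CDKN2A rose from 23 ± 12 to 56.1 (1.29 ± 0.31, adjusted p = 0.0077), whereas CDKN1A fell from 206 ± 25 to 105 ± 1.9 (adjusted p = 0.000153). The cytokine gene IL6 rose from 0.694 to 5.40 and PPARGC1A, a regulator of mitochondrial genes, rose from 4.03 to 19.7 (2.30 ± 0.19). MYC rose by 0.71 (adjusted p = 0.00483). The proliferation gene MKI67 did not pass the threshold (0.43 ± 0.33, adjusted p = 0.287), but passed without primary library 2 (0.84, adjusted p = 0.026). The nuclear lamina gene LMNB1 did not pass (-0.30, adjusted p = 0.237), but without primary library 1 it changed by -0.54 (adjusted p = 0.000162), and under total-count scaling the sign turned to 0.14. TERT, the telomerase gene, had 0 counts in the primary libraries and 2 in the senescent ones together, below the floor of 3 counts, so no fold is given.

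Several of the largest rises started from no counts. CD163L1 was at least 1195-fold higher in senescent than in primary libraries, TRIM63 at least 690-fold, FAM169A at least 353-fold, CNKSR2 at least 318-fold and CHL1 at least 222-fold, against a floor of 3 counts over the group. PPFIA2 had a ratio of 1414 with a 95% counting interval of 254 to 55867. Such bounds and intervals cover counting error only. Among the largest falls, FMOD fell from 345 to 0.527 (-9.34 ± 0.33), BGN from 407 to 0.720 (-9.13) and WISP2 from 787 to 1.49 (-9.04), while CRABP1 was at least 236-fold lower. SLIT3 was lower by a ratio of 2547 (457 to 100610) and BARX1 by a ratio of 750 (135 to 29612).

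Groups of genes moved as follows. Of 33 collagen and matrix genes, 20 fell and 6 rose (adjusted p = 0.00333 with camera, adjusted p = 0.291 with an estimated correlation). ELN fell from 41.0 to 1.04. Of 15 fibroblast marker genes, 13 fell, including DCN (-1.88) and PDGFRA (-1.85), with adjusted p = 0.00333 and adjusted p = 0.129 with an estimated correlation. Markers of some other cell types rose: 6 of 7 chondrocyte and osteoblast genes, such as ACAN (5.18), with adjusted p = 0.0216, and 4 of 5 melanocyte and Schwann genes, such as NGFR (2.99), with adjusted p = 0.0211, both with adjusted p = 0.129 with an estimated correlation. Keratinocyte and epithelial genes (3 of 5 higher, adjusted p = 0.103) and endothelial genes (4 of 6 higher, adjusted p = 0.11) did not pass as lists, nor did pericyte and smooth muscle genes, of which 2 of 9 were higher and 4 lower (median -0.81, adjusted p = 0.414). Of 21 contractile and TGF-beta response genes, 12 fell, ACTA2 by the widest margin (-2.90), with adjusted p = 0.0242 for the list, adjusted p = 0.129 with an estimated correlation and adjusted p = 0.0507 without primary library 2. Antioxidant genes fell in 15 of 22 cases, among them HMOX1 (-1.84) and PRDX3 (-1.95), and 7 of 11 antigen presentation genes rose, such as a BOLA gene (2.58) and TAP1 (2.55). Both lists had adjusted p = 0.129 with an estimated correlation. Immune cell markers also lay higher, with a median change of 1.04 over 6 genes. Of 32 secretory genes of senescence, 16 rose and 11 fell, and the list did not pass (adjusted p = 0.103). HGF rose from 0.106 to 21.6 and IGFBP7 from 6.33 to 202. Of 52 oxidative phosphorylation genes, 39 fell (42 adjusted over the list alone), but the list had adjusted p = 0.455 with an estimated correlation. Primary library 1 stood apart here: its list median lay 1.19 above the senescent mean, against 0.27 and 0.63 in the other primary libraries. Of 23 mitosis genes, 6 rose and 6 fell. AURKB fell by 1.27 while CENPE rose by 0.91.

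In all, 7591 of 13099 genes passed, 3704 higher and 3887 lower (5955 and 1840 under total-count scaling, where 465 of these calls changed sign), and 66.6% of genes had groups that did not overlap, against 10% by chance. Of 31 lists 15 passed, 0 of them with an estimated correlation, and 9 without primary library 2, which ended the calls of DNA replication (adjusted p = 0.0506), interferon response, contractile genes, ribosome biogenesis (adjusted p = 0.14), chromatin proteins and stress response (adjusted p = 0.0515). Interferon response also lost its call without primary library 1 (adjusted p = 0.0793) and stress response without primary library 3 (adjusted p = 0.0542). Under total-count scaling the median of all genes shifted by 0.47, and 11 list medians changed sign, among them those for DNA replication (-0.32), cholesterol synthesis (-0.41), stress response (-0.26), chromatin proteins (-0.32), glycolysis and hypoxia (-0.44), HOX and limb genes (-0.44), lysosome (-0.18), imprinted genes (-0.18), telomere proteins (-0.09) and mitosis (-0.04).

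The comparison of immortalized with senescent Simmental-like libraries asked what set these stages apart. Here too the culture names differ, and a common animal and body site are not stated. The secretory genes of senescence fell: 22 of 32 were lower and 3 higher (adjusted p = 5.6e-07, adjusted p = 0.121 with an estimated correlation). CXCL8 fell from 44.2 ± 1.9 to 0.921 ± 0.15 (-5.58 ± 0.21, adjusted p = 2.0e-06), CCL2 from 160 to 5.71 (-4.81 ± 0.13) and IL6 from 5.40 to 3.19 (adjusted p = 0.01). Medians of some lists of cell type markers lay further down than the -1.34 of the secretory genes: -1.80 for endothelial genes (5 of 6 lower, adjusted p = 0.00233, adjusted p = 0.117 with an estimated correlation), -2.47 for adipocyte genes (4 of 5 lower, adjusted p = 0.0125, adjusted p = 0.206 with an estimated correlation) and -2.39 for immune cell genes (3 of 6 lower, adjusted p = 0.0881). Endothelial and blood cell genes were already low in the senescent libraries. By total counts PECAM1 stood there at 1.64 to 2.16 CPM, VWF at 5.85 to 6.68, CD74 at 0.309 to 0.532 and PTPRC at 0.048 to 0.103. CDKN1A fell from 105 to 62.2, while CDKN2A rose again, from 56.1 ± 0.20 to 138 ± 11 (1.29, adjusted p = 0.0120). CDKN2B stayed at 96.0 and did not pass (adjusted p = 0.392). PPARGC1A fell from 19.7 ± 1.6 to 2.16 ± 0.26 (-3.19 ± 0.20). MKI67, LMNB1 and MYC did not pass, with adjusted p from 0.165 for LMNB1 to 0.691 for MKI67. TERT had 2 counts at either stage.

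Cholesterol synthesis was the list that held under both forms of the test. Of 24 genes 14 rose and 0 fell (16 and 0 adjusted over the list alone), with adjusted p = 5.8e-06 and adjusted p = 0.0413 with an estimated correlation. HMGCS1 rose by 1.38, INSIG1 by 1.19, DHCR7 by 1.16 and IDI1 by 1.13. Of 24 DNA replication genes 13 rose and 0 fell, among them MCM3 (1.08), MCM2 (1.07) and MCM5 (1.04), with adjusted p = 0.000475 and adjusted p = 0.121 with an estimated correlation. Of 23 mitosis genes 8 rose, led by DLGAP5 (1.14) and CCNB2 (1.01). Of 25 stress response genes 13 rose, with CHAC1 from 9.91 to 39.9 and PSAT1 from 249 to 548. Lysosomal genes fell in 16 of 31 cases. CTSZ fell by 7.60 and SQSTM1 by 1.95. Of 24 interferon response genes 8 fell, including IRF7 (-4.05) and IFIH1 (-2.48). The 5 lists from DNA replication to interferon response had adjusted p of 0.121 or above with an estimated correlation.

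The single genes that rose most were ACSS3 (from 0.161 to 24.2, 7.18 ± 0.49), INHBE (6.64), NGFRAP1 (4.96), TSPAN7 (4.90), CNTFR (4.38) and RTN1 (4.21). CPXM (-7.74), CTSZ (-7.60) and the fatty acid carrier FABP4 (-7.44) fell most among genes with enough counts, and TRPC4, SLC32A1 and AJAP1 were lower by ratios of 919 (165 to 36294), 601 (206 to 2913) and 567 (157 to 4678). In total 4249 of 13099 genes passed, 2146 higher and 2103 lower (1505 and 2698 under total-count scaling), and groups did not overlap for 70.9% of genes, against 10% by chance. Total-count scaling shifted the median of all genes by -0.16, and 5 list medians changed sign under another scaling.

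Genes of the same chromosome shifted together between the senescent and the immortalized Simmental-like libraries. Each of the 30 groups below holds all tested genes placed on 1 chromosome, named by its first and last gene. The 336 tested genes from PPFIA4 to TNNT2 had a median change of -0.52, with -0.44, -0.49 and -0.51 in the 3 immortalized libraries. The 320 genes from MRPS24 to KLF15 had 0.50, the 273 from MAGEL2 to TMEM121 had 0.38 and the 500 from MCC to B2M had 0.37. Each chromosome was also cut in the middle of its gene order. The medians of the parts, in the same order, were -0.54 and -0.48, 0.42 and 0.53, 0.38 and 0.37, and 0.24 and 0.54. In the group from GPR83 to ACAD8 the parts differed in sign (-0.09 and 0.35). Of 30 groups 14 passed a permutation test of gene order at 0.05, 7 higher and 7 lower, and the highest median in 1000 permutations was 0.272. Wide medians were also seen from primary to senescent, where this test was not run. They were -0.63 for UBE2D1 to PWWP2B, -0.39 for PRIM2 to DUSP22 and 0.39 for MCC to B2M. For PPFIA4 to TNNT2, MRPS24 to KLF15 and MAGEL2 to TMEM121 they were -0.11, 0.03 and -0.13.

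**Figure D2:**
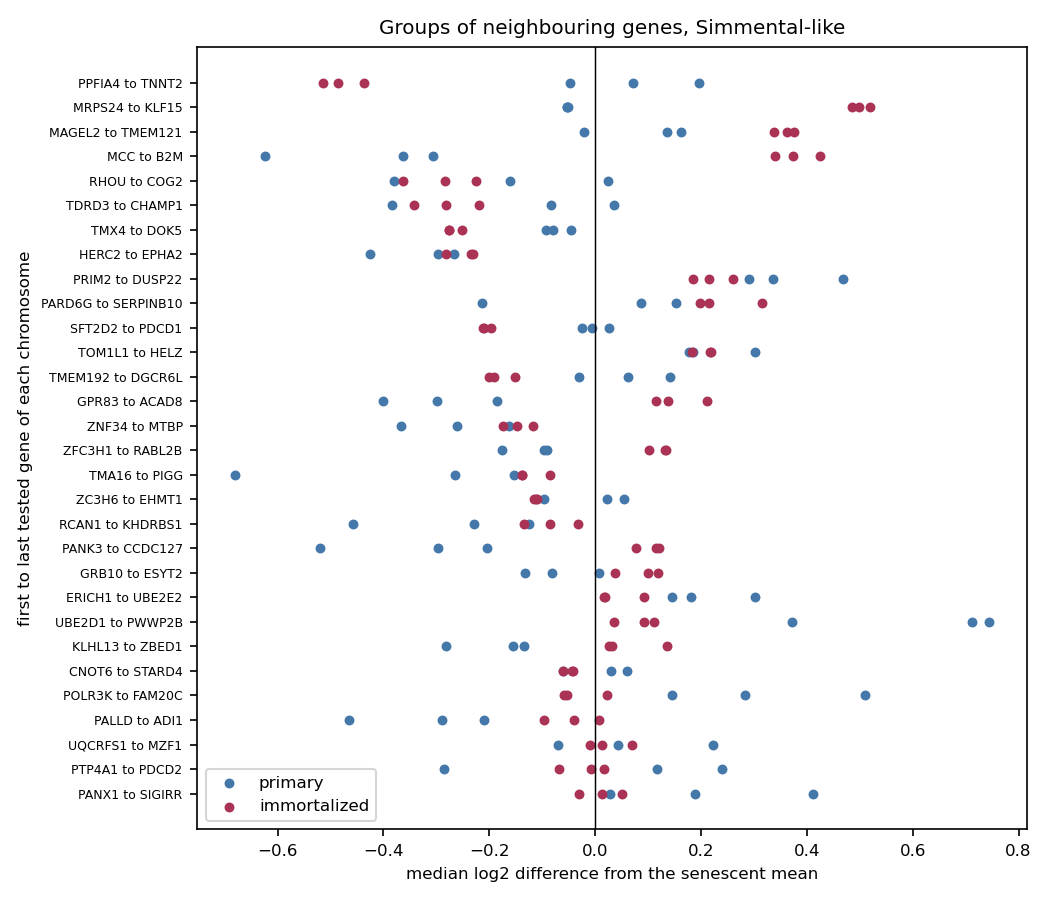
Median log2 difference from the mean of the 3 senescent libraries for each group of neighbouring genes, with 1 point per primary and immortalized Simmental-like library. Each group is all tested genes placed on 1 chromosome, named by its first and last tested gene. The group from PPFIA4 to TNNT2 lies at -0.44, -0.49 and -0.51 in the immortalized libraries.

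**Figure D3:**
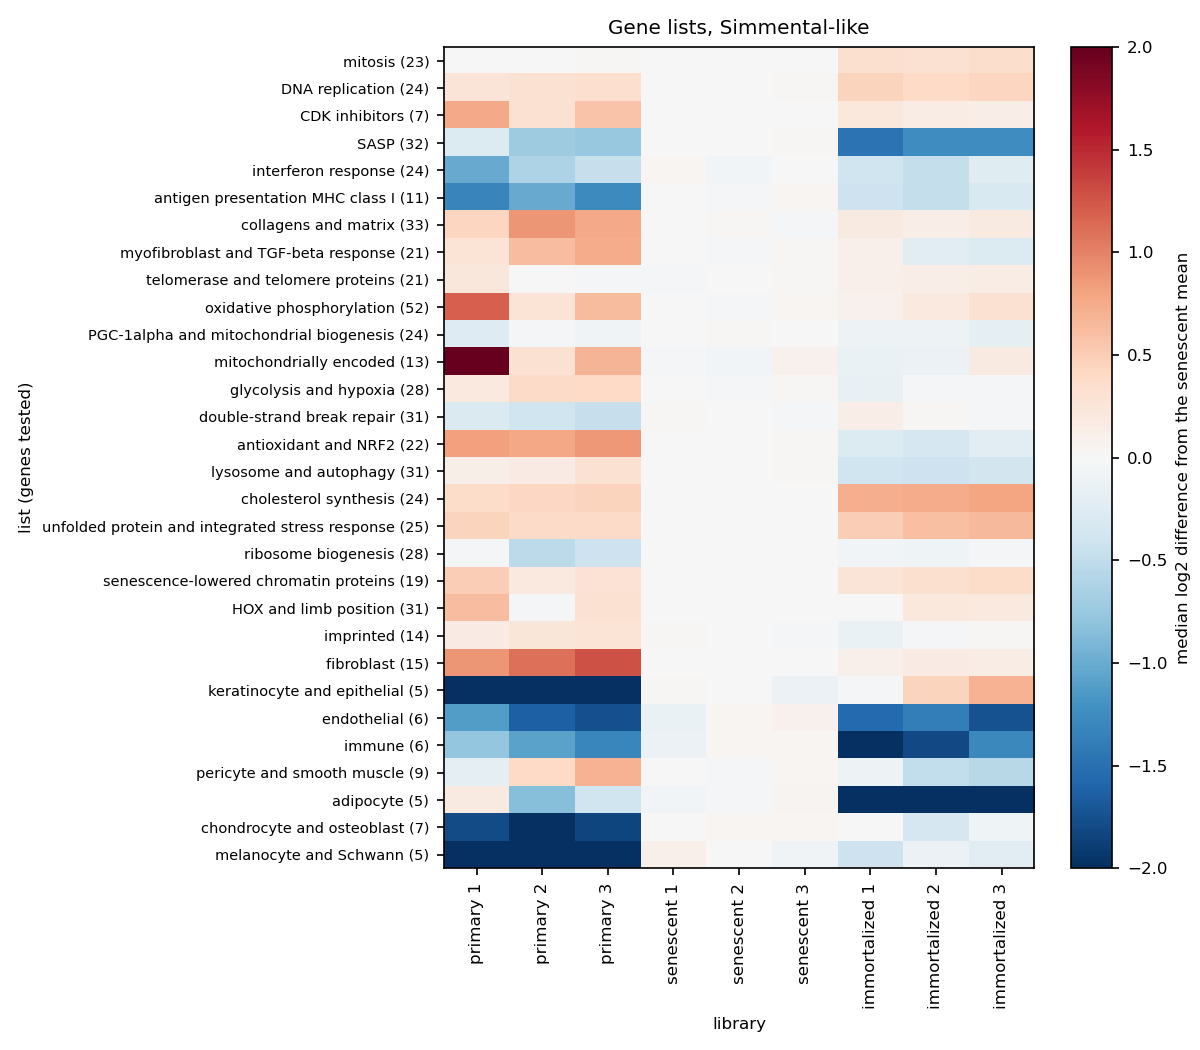
Heatmap of the median log2 difference from the mean of the 3 senescent libraries, for 30 gene lists (vertical axis) in each Simmental-like library (horizontal axis), with colours ending at 2 in either direction. The secretory genes of senescence (SASP) lie between -1.48 and -1.24 in the immortalized libraries and the mitosis genes between 0.31 and 0.36.

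Immortalized and primary Simmental-like libraries were compared to ask how far apart the first and the last stage lay. As in the other Simmental-like comparisons, the columns carry different culture names. The sources used here do not say whether both stages came from 1 animal and body site. They kept the higher growth inhibitor genes: CDKN2A was at 138 ± 11 against 23 in primary libraries (2.58 ± 0.32, adjusted p = 0.000247) and CDKN2B at 96.0 against 17.7 (2.43 ± 0.15). CDKN1A was lower (62.2 against 206 ± 25, -1.73 ± 0.11, adjusted p = 4.9e-06) and MYC higher (0.92, adjusted p = 0.00135). IL6 was higher by 2.22 and PPARGC1A lower (-0.89, adjusted p = 0.00641). MKI67 did not pass (0.62, adjusted p = 0.148) but passed without primary library 2 (1.03, adjusted p = 0.0125). LMNB1 did not pass (0.11, adjusted p = 0.672) and turned to -0.14 without primary library 1. TERT had 0 counts in primary and 2 in immortalized libraries.

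FAM169A, RORB, CNKSR2, RTN1 and TFAP2B had no counts in primary libraries and were at least 513-fold, 437-fold, 353-fold, 314-fold and 243-fold higher in immortalized ones. DSG2, a desmosome gene, rose from 0.0749 to 285 (11.74 ± 0.21). BGN fell from 407 to 0.0660 (-12.45), FAM180A, NUDT16 and CAMK1G were at least 1062-fold, 439-fold and 412-fold lower, and FMOD and ALDH1A1 were lower by ratios of 10373 (2872 to 85651) and 2992 (1024 to 14506). Of 22 antioxidant genes 15 fell and 0 rose (adjusted p = 0.000311, adjusted p = 0.105 with an estimated correlation), with GPX3 at -4.46 and HMOX1 at -3.20. Of 31 double-strand break repair genes 14 rose and 1 fell (adjusted p = 0.0173, adjusted p = 0.260 with an estimated correlation). XRCC2 (1.10) and FANCD2 (1.02) were among them. Of 31 lysosomal genes 19 fell, of 28 ribosome biogenesis genes 11 rose, and of 28 glycolysis and hypoxia genes 13 fell, including SLC16A3 (-5.62) and EGLN3 (-4.60). Ribosome biogenesis did not pass without primary library 2 (adjusted p = 0.0611). These 3 lists had adjusted p of 0.184 or above with an estimated correlation. Of the cell type lists, fibroblast markers (10 of 15 lower, adjusted p = 0.0196), chondrocyte and osteoblast genes (5 of 7 higher, adjusted p = 0.0269) and melanocyte and Schwann genes (3 of 5 higher, adjusted p = 0.0310, but adjusted p = 0.0785 without primary library 1) passed, with adjusted p of 0.184 or above with an estimated correlation. Altogether 6607 genes passed, 3264 higher and 3343 lower (4580 and 2098 under total-count scaling, where 54 of these calls changed sign), 56.3% of genes had groups that did not overlap (10% by chance), and total-count scaling shifted the median of all genes by 0.30. Under another scaling 4 list medians changed sign.

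**Figure D4:**
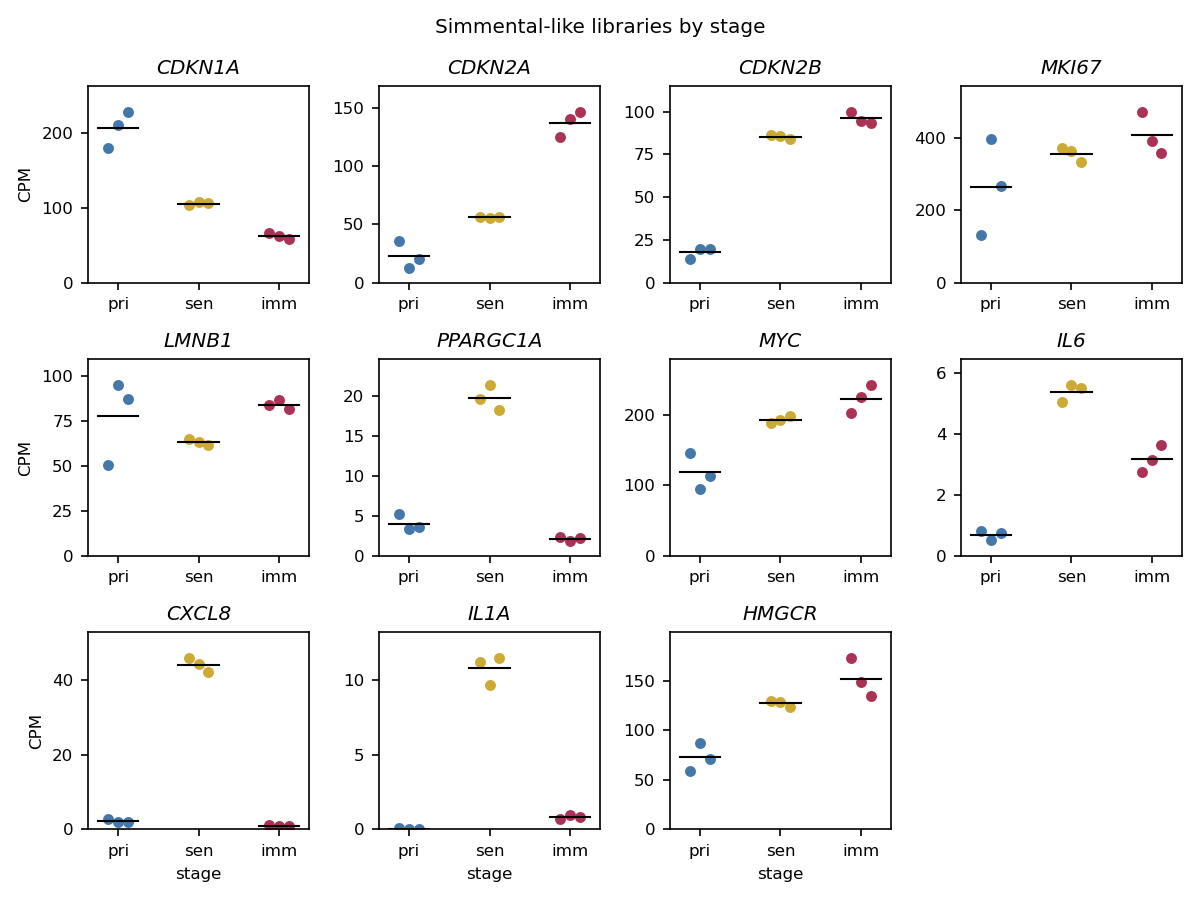
Levels of 11 genes (CPM, TMM scaling, vertical axis) in the Simmental-like primary (pri), senescent (sen) and immortalized (imm) libraries, with 1 point per library and a bar at the mean. CDKN2A rises from 23 through 56.1 to 138, and CDKN1A falls from 206 through 105 to 62.2.

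Between the libraries labelled Holstein-like senescent and primary, 5 of 11 skeletal muscle genes fell and 0 rose (adjusted p = 2.2e-08, adjusted p = 0.820 with an estimated correlation). MYH1 fell from 83879 to 5.22, ATP2A1 (-13.75) and MYH2 (-13.32) fell with it, and the plasma protein genes CP and TTR were at least 2677-fold and 1108-fold higher in the libraries labelled senescent. Of 28 interferon response genes 21 rose, with IFI6 higher by a ratio of 328 (112 to 1590), and of 22 HOX and limb genes 10 fell, HOXA10 at least 373-fold. Both lists had adjusted p = 0.833 with an estimated correlation. None of CDKN1A (0.85, adjusted p = 0.203), CDKN2B, MKI67, LMNB1 (1 count in primary libraries, a ratio of 10.97, 1.97 to 433, adjusted p = 0.0679), PPARGC1A and MYC (-1.35, adjusted p = 0.105) passed. TERT, CDKN2A and IL6 were not tested in this line, since they did not meet the count filter. Over the 3 primary, senescent and immortalized libraries TERT had 0, 8 and 63 counts, CDKN2A had 0, 17 and 32, and IL6 had 0, 2 and 7. These sums rested mostly on single libraries. TERT stood at 5.46 CPM by total counts in immortalized library 2, which carried kidney transcripts, and at 0.084 and 0.143 in libraries 1 and 3. CDKN2A stood at 2.35 CPM in immortalized library 1 and at 0 and 0.286 in libraries 2 and 3. The floor of 3 counts was 0.689 CPM over the primary libraries, against 0.0744 and 0.0813 over the later ones. Of 13312 genes 2024 passed, 1239 higher and 785 lower (1707 and 409 under total-count scaling, 124 and 663 with limma-voom, 29 and 117 without primary library 1), and 51.5% had groups that did not overlap (10% by chance). The count changed with each library left out: it was 146, 154 and 143 without primary library 1, 2 or 3, and 3545, 272 and 362 without senescent library 1, 2 or 3. No single primary library carried the count, since it fell alike without any of them. The primary libraries differed by little more than counting noise (chi-square per gene 1.17 to 1.21), but the tests count them as 3 replicates. Of 82 calls for named genes, 73, 72 and 72 ended without primary library 1, 2 or 3, and 3, 64 and 62 without senescent library 1, 2 or 3. The median of all genes lay 0.62 above 0, and 0.99 above it under total-count scaling. Of 31 lists 9 passed, and 0 with an estimated correlation.

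Between the libraries labelled Holstein-like immortalized and senescent, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with 972 at an unadjusted p under 0.05, and DESeq2 called 34. CDKN1A had the change closest to the threshold among the key genes along with MYC (-1.66 and 1.64, adjusted p = 0.652 for both). Groups did not overlap for 6.66% of genes, against 10% by chance. Of 31 lists 12 passed, such as oxidative phosphorylation (52 genes, 0 called, adjusted p = 7.1e-11) and mitosis (15 genes, 0 called, adjusted p = 0.000115), but with an estimated correlation the values were adjusted p = 0.703 and adjusted p = 0.413. Without immortalized library 1 the count of genes was 5. Total-count scaling shifted the median of all genes by 0.53.

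Of 11 skeletal muscle genes, 7 were lower and 0 higher in the libraries labelled Holstein-like immortalized than in the primary ones (adjusted p = 9.1e-08, adjusted p = 0.506 with an estimated correlation). MYH1 (-18.92) and CKM (-17.03) fell, MYL1 was at least 102850-fold lower, and IGLL1, GPNMB and SPP1 were at least 1109-fold, 915-fold and 403-fold higher. LMNB1 rose from 1 count to 4.46 ± 1.2 (a ratio of 14.5, 2.61 to 575, adjusted p = 0.0395), and CDKN2B, MKI67, PPARGC1A and MYC did not pass. CDKN1A did not pass either (-0.81, adjusted p = 0.193) and turned to 0.08 under total-count scaling. Of 12 immune cell genes 11 rose, among them CD14 (6.24), and of 31 lysosomal genes 14 rose, among them LIPA (5.12) and CTSZ (4.76). These lists had adjusted p of 0.506 or above with an estimated correlation. Of 13312 genes 3198 passed, 2036 higher and 1162 lower (236 and 912 with limma-voom, 4778 and 545 under total-count scaling, 204 and 324 without primary library 1), with 55.4% of genes not overlapping (10% by chance). The count was 528, 511 and 417 without primary library 1, 2 or 3, and 1762 and 2127 without immortalized library 1 or 2. Of 103 calls for named genes, 90, 89 and 91 ended without primary library 1, 2 or 3, and 45 and 39 without immortalized library 1 or 2. The median of all genes lay 0.74 above 0, and 1.68 above it under total-count scaling.

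The lines were then set side by side to ask which changes they shared. From primary to senescent, 3 genes of desmosome proteins were among the 6 largest shared rises: DSG2 by a ratio of 228 (40.9 to 9000) in Holstein-like libraries and by 9.83 in Simmental-like ones, DSP by 7.32 and by a ratio of 205 (70.1 to 993), and PKP2 at least 142-fold and by a ratio of 605 (167 to 4992). No list of desmosome genes was tested. The Holstein-like primary libraries carried muscle transcripts, and the senescent ones carried heart (library 1) or liver transcripts (libraries 2 and 3). Stage and organ transcripts therefore cannot be told apart in the shared changes. Over the Holstein-like and Simmental-like primary libraries DSG2 had 1 and 4 counts, DSP 7 and 3 and PKP2 0 and 2. PERP, CRYM and RASSF5 were also higher in both. The HOX genes HOXA10, HOXC6 and HOXA9, with BIN1, DHDH and the early response gene NR4A1, were lower in both. In all 417 of 11711 genes changed the same way, 284 higher against 309 if the lines were independent and 133 lower against 218, and 671 changed in opposite ways against 551. Pearson's r across genes was 0.05 and Spearman's rho -0.05, and genes are not independent replicates. The count was 13, 14 and 14 without Holstein-like primary library 1, 2 or 3, and 854, 43 and 49 without senescent library 1, 2 or 3. From senescent to immortalized 0 genes were shared by edgeR's test, because 0 passed in the Holstein-like line (972 at an unadjusted p under 0.05), and DESeq2 gave 11. From primary to immortalized DSG2, SPP1, GRP, PERP, FAM149A and RASSF5 were higher in both and TPM2, NR4A1, JPH2, HSPB8, ALDOA and ALPK3 lower in both. Here 638 genes changed the same way, 432 higher against 428 and 206 lower against 274, and 870 changed in opposite ways against 733. That count was 81, 68 and 60 without Holstein-like primary library 1, 2 or 3, and 340 and 374 without immortalized library 1 or 2.

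The change itself differed between the lines for many genes, which the organ transcripts of the Holstein-like libraries accompany. BGN rose by 3.73 from primary to senescent in the Holstein-like libraries and fell by 9.13 in the Simmental-like ones (difference 12.91 ± 0.68, adjusted p = 9.2e-08). ARPP21 went the other way (difference -15.26 ± 0.82), as did CNKSR2, whose change was at least 10914-fold lower in the Holstein-like libraries. CDKN1A differed by 1.87 ± 0.48 (adjusted p = 0.0104), MYC by -2.01 ± 0.55 and LMNB1 by a ratio of changes of 13.5 (2.42 to 532, adjusted p = 0.0113). MKI67, CDKN2B and PPARGC1A did not pass. From primary to immortalized the differences included those of BGN (16.62) and CTSZ (16.11), the change of GPNMB was at least 6339-fold higher in the Holstein-like libraries and that of ARPP21 lower by a ratio of 339990 (94119 to 2807400), and LMNB1 was the key gene that passed (a ratio of changes of 13.5, 2.42 to 532, adjusted p = 0.0101). For CDKN1A and MYC that comparison passed only without Holstein-like immortalized library 2 (1.28 for CDKN1A) or 3 (-1.36 for MYC). Of 14850 genes 4217 differed from primary to senescent, 308 from senescent to immortalized and 4808 from primary to immortalized. These tests gave each gene 1 dispersion for both lines, though the common coefficient of variation was 0.748 in the Holstein-like and 0.209 in the Simmental-like fit. With such sharing, calls from primary to senescent went from 2024 to 5203 in the Holstein-like line and from 7591 to 2025 in the Simmental-like one. The counts and p-values of the differences depend on it. The 308 became 674 and 630 without Holstein-like senescent library 1 or 3, 1352 and 499 without immortalized library 1 or 2, 100, 91 and 96 without Simmental-like senescent library 1, 2 or 3, and 69, 70 and 39 without immortalized library 1, 2 or 3. From senescent to immortalized no key gene passed, the lowest adjusted p being 0.164 for MYC, but MYC passed without Holstein-like immortalized library 1 (1.87, adjusted p = 0.0150). Line and sequencing run could not be separated, since the column names of the Holstein-like libraries mark them as rerun.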

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

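The counts and genes given first stand out because the change between stages differed between the lines, and 2 further patterns concern the Simmental-like line alone. Each test of an explanation below was chosen after the result was seen. With 1 dispersion per gene shared by both lines, the count of genes that differed was 4217 from primary to senescent, 308 from senescent to immortalized and 4808 from primary to immortalized. Of 60 splits, the real one and others drawn at random from all combinations of the splits of both lines, 1 had a count as large as 4217 (highest other 2099), 5 had one as large as 308 (highest other 1033) and 1 had one as large as 4808 (highest other 2988). A split that called 1033 where the stages called 308 points to a structure of the samples other than stage. The 2099 and the 2988 came from splits that kept the real Holstein-like stages. Other splits mix the stages within a line, so these counts cannot test whether the 2 lines changed alike.

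Where a group had 0 counts, the ratio of the Holstein-like to the Simmental-like change is given as a lower bound against 3 counts over the group, and with 1 to 3 counts it is given with a 95% counting interval.

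From primary to senescent, the change of HOXA10 was at least 147-fold and that of HOXC6 at least 75.3-fold lower in the Holstein-like libraries. The differences (Holstein-like minus Simmental-like log2 change) were -5.85 for HOXA9, -4.33 for BIN1, -5.65 for DHDH and -2.17 for NR4A1. These 6 genes were lower in both lines. The difference was 12.91 for BGN, and the change was at least 1209-fold higher in the Holstein-like libraries for POSTN, 53.9-fold for RARRES1, 33.0-fold for BPHL, 20.3-fold for FAM46A and 21.4-fold for NIPAL2. For genes that fell in the Holstein-like and rose in the Simmental-like libraries the differences were -15.26 for ARPP21, -9.88 for HIST1H2AC and -9.50 for HK2, and the change of CNKSR2 was at least 10914-fold lower in the Holstein-like libraries. CDKN1A differed by 1.87 and MYC by -2.01, and the change of LMNB1 was higher by a ratio of 13.5 (2.42 to 532).

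From primary to immortalized, the change of SPP1 was at least 148-fold and that of FAM149A at least 13.8-fold higher in the Holstein-like libraries, both genes being higher in each line. The differences were -6.35 for TPM2, -2.96 for HSPB8, -4.72 for ALDOA and -4.99 for ALPK3, lower in each line. FAM149A no longer passed without most single libraries (adjusted p from 0.0619 to 0.0824). BGN differed by 16.62 and CTSZ by 16.11, and the change was at least 6339-fold higher in the Holstein-like libraries for GPNMB, 813-fold for RARRES1, 357-fold for HSD17B14 and 324-fold for IFI30. The change of CNKSR2 was at least 14295-fold lower and that of ARPP21 lower by a ratio of 339990 (94119 to 2807400). ACTN3 differed by -13.72, PRKCQ by -11.04, CAP2 by -10.26 and SEMA4D by -9.98. The change of LMNB1 was higher by a ratio of 13.5 (2.42 to 532).

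Organ transcripts in the Holstein-like libraries bear on all of these differences. If the stage of culture set the profiles, libraries should lie nearest to their own stage, but 1 of the 6 senescent and immortalized libraries did. If tissue RNA had been mixed into fibroblast RNA, fibroblast genes should remain, but in 8 libraries their share was at most 12.8% of the lowest Simmental-like one. Whether columns hold other samples than their labels stays open, since the 8 libraries in which an organ set took more counts than the fibroblast set are the observation itself and cannot test it. For immortalized library 3, where MKI67 stood at 12.2% of the lowest Simmental-like library, a mixture and a tissue cannot be told apart.

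Of the 14 shifted groups of neighbouring genes in the Simmental-like immortalized libraries, the 4 with the widest medians were weighed in the same way. A chance order of genes gave at most 0.272, below the size of these 4 medians, from 0.37 (MCC to B2M) to 0.52 (PPFIA4 to TNNT2). Some of the other groups that passed lay under 0.272, down to 0.16 for GPR83 to ACAD8. Bias by expression level and gene length is argued against by the 83.2% or more of each of the 4 widest medians that was kept after a fit on both. That does not cover the other groups: the median from RHOU to COG2 went from -0.31 to -0.17 after the fit. A single immortalized library is argued against by the smallest median of 0.339 that any of these 4 groups had in any of the 3 libraries. Each group is a whole chromosome, and gains and losses of chromosome copies were not tested here and stay open.

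Mitosis genes were not lower in the Simmental-like senescent libraries than in the primary ones (median -0.04, 6 up and 6 down of 23), and under total-count scaling 13 were higher and 1 lower (median 0.43), against 7 and 3 under upper quartile scaling. Without primary library 1 the median was -0.0205, with 7 genes higher and 7 lower, so the list was not lower without that library either. The lowest median under the other scalings was -0.0524 (RLE, 5 higher and 6 lower). The tally by direction depended on the scaling, and a small median over members that moved both ways cannot decide what normalization did. By total counts MKI67 stood at 231 ± 134 CPM in primary, 414 ± 23 in senescent and 423 ± 61 in immortalized libraries. It was thus not low in the libraries labelled senescent. The mitosis list as a whole lay higher in immortalized than in senescent libraries (median 0.27). Whether the cells labelled senescent were still dividing when harvested stays open, since division itself was not measured.

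The same libraries were also split in other ways. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, so only the real value and the highest other are given. For genes in the Holstein-like line, 1 split reached the real 2024 from primary to senescent (highest other 0), 10 reached the real 0 from senescent to immortalized (highest other 1341) and 1 reached the real 3198 from primary to immortalized (highest other 0). The 1341 came from the split that put the 3 libraries rich in liver transcripts together, which points to a structure of the samples. In the Simmental-like line 1 split reached the real count each time, which was 7591, 4249 and 6607 (highest other 0 each time). For lists, 7 splits reached the real 9 (highest other 18), 5 the real 12 (13) and 7 the real 12 (13) in the Holstein-like line, and 1 the real 15 (7), 2 the real 10 (12) and 1 the real 11 (6) in the Simmental-like line. For genes changed the same way in both lines, of 100 splits 2 reached 417 (highest other 671), 100 reached 0 (246) and 2 reached 638 (870). The 671 and 870 came from the real split with 1 line mirrored.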

How the results depend on the processing

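Among Simmental-like named genes, 2261 results stayed the same when a library was left out, 153 became weaker, 3 became stronger and 1 reversed, and under other settings the numbers were 3895, 324, 3 and 1. For Holstein-like named genes they were 463, 739, 1 and 8, and 1816, 532, 4 and 8. For differences between lines they were 731, 11, 9 and 17, and 355, 2, 13 and 10. For lists they were 377, 37, 0 and 0, and 237, 103, 0 and 0. Thinning, summed primary libraries and summed senescent libraries 1 and 2 were chosen after seeing the data. Depth limits the Holstein-like primary libraries, where 3 counts are up to 2.11 CPM. The main fits did not pair samples by replicate number. Not every sample correlated best with its own number, but with 3 libraries per stage that cannot decide whether the numbers pair the samples. Where no cause is named below, the cause was not tested.

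Holstein-like genes from primary to senescent numbered 2024, but 3942 with DESeq2, 787 with limma-voom, 303 with a replicate block (111 higher, 192 lower), 5203 in a fit of all 18 libraries, 0 with the primary libraries summed, and 143 to 3545 leaving out a library. Thinning gave 1973. From senescent to immortalized they numbered 0, but 34 with DESeq2, 4 with 18 libraries and 0 to 5 leaving out a library. From primary to immortalized they numbered 3198, but 5323 with total-count scaling, 4938 with DESeq2, 1148 with limma-voom, 1109 with a replicate block, 6628 with 18 libraries, 0 with the primary libraries summed and 417 to 2302 leaving out a library. Thinning gave 2956. Summing leaves 1 primary library. It cannot separate the effect of fewer samples from that of counting near-identical libraries as replicates.

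Simmental-like genes numbered 7591, 4249 and 6607. In a fit of all 18 libraries they numbered 2025, 416 and 1800, and with a 2-fold minimum 4077, 1890 and 3521. Only the 6 libraries compared gave 8600 from senescent to immortalized. Leaving out a library gave 5838 to 9042, 2888 to 3423 and 5191 to 8282. Summing senescent libraries 1 and 2 gave 5943 and 2970.

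Genes changed the same way in both lines numbered 417, but 874 with DESeq2, 39 with a replicate block, 226 with a 2-fold minimum and 13 to 854 leaving out a library. From senescent to immortalized DESeq2 gave 11, and leaving out a library 0 to 0. Those from primary to immortalized numbered 638, but 1077, 169, 318 and 60 to 847. Differences between lines from senescent to immortalized numbered 308, but 600 with total-count scaling, 1187 with DESeq2, 98 with a replicate block and 39 to 1352 leaving out a library. The other 2 ranges were 3224 to 5151 and 3861 to 4879.

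Lists passed 9, 12 and 12 times in the Holstein-like line, but 0 times each with an estimated correlation, 1, 2 and 4 times with fry, and 7 to 11, 9 to 15 and 9 to 17 times leaving out a library. In the Simmental-like line they passed 15, 10 and 11 times, but 0, 1 and 0 times with an estimated correlation, 25, 22 and 24 times with fry, and 9 to 17, 10 to 11 and 11 to 12 times leaving out a library.

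Reversed Holstein-like genes were MKI67 from primary to senescent (-0.23 with limma-voom, -0.26 to 0.91 leaving out a library), and from senescent to immortalized CDKN2B (-1.003 with limma-voom, -0.66 with a replicate block, -0.0161 with 6 libraries, -0.64 to 0.57) and PPARGC1A (0.32 with total-count scaling, -2.55 to 0.78). From primary to immortalized they were CDKN1A (0.0809 with total-count scaling), PPARGC1A (-0.10 with limma-voom, -1.33 to 1.34) and MYC (-0.00866 with limma-voom, -0.65 to 0.65).

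The reversed Simmental-like gene was LMNB1 from primary to senescent (0.14 with total-count scaling) and from primary to immortalized (-0.14 to 0.28).

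Differences of DSG2 and DSP are fitted values with at most 3 counts in a group, so they are no bounds. Reversed differences between lines from primary to senescent were DSG2 (-2.54 to 3.88), DSP (0.25 with a replicate block, -0.77 to 1.04) and MKI67 (-0.0382 with RLE, -0.0365 with DESeq2, -0.15 with a replicate block, -0.72 to 0.54). From senescent to immortalized they were LMNB1 (0.68 with total-count scaling, 0.0459 without a filter, 0.0252 with a stricter filter, 0.11 with a replicate block, -0.35 to 0.36) and CDKN2B (0.36 with total-count scaling, -0.72 to 0.46). Those from primary to immortalized were DSG2 (-5.14 to 1.28), PPARGC1A (-0.15 to 2.38) and MYC (0.11 with total-count scaling).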

Other observations

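Some genes that mark body position differed between the Simmental-like primary libraries and the later ones. They were chosen after their values were seen. The fixed list of HOX and limb genes had medians of 0.61, -0.03 and 0.31 from the senescent mean in primary libraries 1, 2 and 3. Its median change from primary to senescent was -0.44, and 0.04 under total-count scaling. PITX1 went from 2.54 CPM in primary to 46.3 in senescent and 43.7 in immortalized libraries, and GATA4 from 0.228 to 44.8 and 51.9 (7.56 from primary to senescent). HOXD13 went from 0.263 to 3.33 and 6.70. EMX2 fell from 142 to 24.6 and stood at 30.9, and BARX1 fell from 10.96 to 1 count in the senescent libraries together and 0 in the immortalized ones. Whether the primary cultures came from another animal or body site was not tested and cannot be told apart from stage.

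Genes with at most 3 counts in a stage and at least 1 CPM in another were counted in the Simmental-like line. From primary to senescent 177 were seen only later and 22 only earlier. From senescent to immortalized the numbers were 13 and 76, and from primary to immortalized 171 and 98. Genes in the group from UBE2D1 to PWWP2B were higher in the 3 primary than in the senescent libraries, with medians of 0.37, 0.74 and 0.71.

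Mitochondrially encoded genes took 9.92% of the counts in Simmental-like primary library 1, 2.50% and 3.12% in the other primary libraries and 2.11% to 2.72% in the later ones. In the Holstein-like libraries they took 5.73% to 5.82% in primary, 27.7%, 5.49% and 3.14% in senescent and 4.48%, 18.02% and 7.00% in immortalized libraries.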
